A study of Arabidopsis thaliana with 4 samples.

How the data were processed

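MicroRNA (miRNA) levels were measured in whole seedlings of Arabidopsis thaliana on 4 single-colour arrays, 1 for each combination of genotype (wild type or transgenic for ABR17, an abscisic acid-responsive gene of pea) and NaCl (0 or 100 mM in the growth medium). Per the labels' protocols, seedlings were grown for 2 weeks (the growth text also gives 7 days), total RNA was isolated with TRI-Reagent and enriched for small RNA by precipitation, and a service provider attached an adapter to the 3' ends of the RNA and stained it with Cy3. The groups are called WT_control, WT_salt, ABR17_control and ABR17_salt and were taken from the labels. The design text speaks of 3 biological replicates, while each group has 1 array here. Whether that array holds RNA pooled from the replicates is not given in the sources used here.

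Each of the 4 array files lists 3968 spots. The deposited mean density of a spot is its Cy3 intensity on a linear scale, per the file headers, with no background subtracted: blank spots read well above 0. The scanner and image software are not given in the sources used here. The deposited density SD of each spot (also an intensity) was not used. Of the spots, 2556 carry probes for 213 miRNAs at 12 repeat spots each, 1120 are blank, 268 carry calibration probes and 24 carry 6 probes for 5S rRNA. The authors also deposited a table with 1 processed intensity per miRNA and array, whose method of background correction and scaling is not given in the sources used here. Over the miRNAs detected on an array, its log2 values correlated with the log2 of the spot means after subtraction of the blank mean at r = 0.987 for WT_control, 0.993 for WT_salt, 0.998 for ABR17_control and 0.999 for ABR17_salt. Its column medians were 12.6, 10.3, 11.2 and 9.38 in the same order. The values are therefore linear and uncentred, and the scaling between arrays stays unknown.

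The choices that follow were made before the data were examined, except where stated. Spot intensities were corrected with the normexp method of limma (version 3.58.1 in R 4.3.3, offset 50) over all spots of an array, transformed to log2, averaged over the 12 repeat spots and quantile normalised over the 213 miRNAs. The offset draws differences of dim miRNAs towards 0. Quantile normalisation gives the same rank the same value on every array. A difference of exactly 0 is therefore a tie of rank, not a measured equality, and list medians of 0.00 can rest on such ties. Among bright miRNAs a difference is a step between ranks, which its spot SE does not cover. A miRNA was called detected on an array where at least 50% of its spots lay above the blank mean plus 3 blank SD. Where it was detected on 1 of the arrays compared, the other array entered at the higher of its own value and the lowest detected value of that array, and the difference is given as a bound ("at least"). It was decided after the data were seen that such a bound gives a value only where the array with the detected miRNA was the brighter one, and that list medians use members detected on both arrays.

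With 1 array per group no test between conditions was made. A fit of genotype plus salt would have to take the difference between the salt responses, itself a question of the series, as its only error term. No p-value is given for any comparison of groups. A miRNA was counted as higher or lower where it was detected on at least 1 of the arrays, differed by at least 1 on the log2 scale (2-fold) and had no overlap between the repeat spots of the arrays compared. The SD and SE quoted beside levels and differences come from the 12 repeat spots. They measure the spotting and the scan of 1 hybridisation, not the spread between seedlings, and the number of arrays limits the precision. A difference between salt responses was counted at a size of at least 1 on the log2 scale, and the text sets apart the case where both responses are bounds. The salt responses of the genotypes were also correlated across the miRNAs detected on all 4 arrays. These are not independent replicates, and the SD of that correlation comes from 200 resamples of the repeat spots. Lists of miRNA families were fixed by family number: 13 lists for salt, copper, phosphate and sulfate, auxin signalling, phase change, leaf and meristem development, MYB targeting, small RNA pathway feedback, NF-Y targeting, GRAS targeting, tasiRNA and PPR targeting, conserved families and all other families. The median of a list is given with its percentile among 10000 random lists of the same size, drawn from the 10 miRNAs nearest in mean level on each side, as a description of these arrays. It was left out for lists with fewer than 3 members detected on both arrays. The random lists were drawn with replacement from miRNAs detected on both arrays, members of the list included. The percentile of a list that holds most of these miRNAs, such as the conserved families, is therefore pulled towards the middle. Conserved and other families divide the same miRNAs, so their percentiles are not separate descriptions.

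The miRNAs named in the text were set by rule: the counted miRNAs of each comparison, up to 10 in each direction, the 10 with the largest difference between salt responses, up to 4 members of each list with the largest difference, and the 5 brightest. Any other miRNA named was chosen after its values were seen, and this is said beside it. Sequences and names are those of the array files. Of the 213 miRNA names, 210 matched 1 gene symbol of the NCBI RefSeq annotation of assembly TAIR10.1, from which the locus identifiers were taken. A mature miRNA can come from more loci than the 1 in its name.

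The steps were tested on simulated data: 10 sets of 4 arrays of 213 miRNAs, with blank levels and a spot spread taken from the real arrays. In the comparison simulated for WT_salt and WT_control, the rule found 28 of 30 miRNAs raised 4-fold, 13 of 30 raised 2.5-fold, 22 of 30 lowered 4-fold and 14 of 30 lowered 2.5-fold, and it counted 3 of 431 unchanged ones. For ABR17_salt and ABR17_control it found 28 of 30 raised 4-fold, 18 of 30 raised 2.5-fold, 22 of 30 lowered 4-fold and 9 of 30 lowered 2.5-fold, and counted 4 of 526 unchanged ones. A true 4-fold rise (2 on the log2 scale) was estimated at a median of 1.54 and 1.55 in these comparisons, so the processing understates such changes. Among unchanged miRNAs, 0 of 365 were counted for ABR17_control and WT_control and 0 of 463 for ABR17_salt and WT_salt. The low counts among unchanged miRNAs cover only blank levels and spot spread, which the simulated sets took from the real arrays. They cannot tell how often a difference in hybridisation or between seedlings would be counted. In both salt comparisons the simulated rises and falls were equal in number, at 30 each for 4-fold and for 2.5-fold. The shares found therefore do not cover changes that run mostly in the same direction. These shares were not split by level, so they do not show how well changes of dim miRNAs were found.

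Results were recomputed under 11 alternatives fixed beforehand (no background correction, a normexp offset of 16, scaling on the 75th percentile, cyclic loess, no normalisation between arrays, the authors' deposited values, the median of repeat spots, 3 other detection filters, and no requirement on spot overlap) and 4 added after seeing the data (the blank mean subtracted, scaling on the calibration probes with names ending in 3P, normalisation without the WT_control array, and a detection threshold from the dimmest calibration probes). Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.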

Results

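The expression of 213 miRNAs was measured in seedlings of wild type Arabidopsis and of plants carrying ABR17, a gene of the pathogenesis-related PR10 family that responds to abscisic acid in pea, grown without added salt or with 100 mM NaCl. Each combination was represented by 1 array, so no difference described here has a replicate check. The series asks how miRNAs take part in gene regulation of the transgenic plants under salt stress. The design therefore gives 4 comparisons: salt against no salt within each genotype, and transgenic against wild type within each medium. The salt responses of the genotypes are also set against each other.

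Of the 213 miRNAs, 63 were detected on at least 1 array and 30 on all 4, whereas 150 were detected on none. WT_control had 39 detected miRNAs, WT_salt 54, ABR17_control 30 and ABR17_salt 59. Families conserved among land or flowering plants made up most of them: 40 of 49 conserved probes (81.6%) were detected on at least 1 array, against 23 of 164 probes (14.0%) of other families. The 5 brightest probes, a matter of probe as well as of abundance, were detected on every array. They were those of miR854a (AT5G04995, sequence GAUGAGGAUAGGGAGGAGGAG; mean normalised log2 intensity 11.87), miR166a (10.64) and miR165a (10.20), which target the class III homeodomain-leucine zipper genes of leaf polarity, miR161.1 (10.24), which targets pentatricopeptide repeat (PPR) genes, and miR156a (10.10), which targets SPL factors and keeps seedlings juvenile. As the top probe of each array, miR854a is fixed at 1 value by the quantile normalisation, and miR166a held 1 value on every array as well. Their differences of 0 do not show unchanged levels. In the authors' deposited values miR854a read 7449 on WT_control, 2753 on WT_salt, 2913 on ABR17_control and 3152 on ABR17_salt. There miR166a read 1797, 1407, 1699 and 1326 in the same order.

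The arrays differed in brightness outside the miRNA probes. Blank spots averaged an intensity of 231 ± 22.2 (SD of 1120 spots) on WT_control, 84.8 ± 5.52 on WT_salt, 111 ± 13.2 on ABR17_control and 86.5 ± 3.92 on ABR17_salt. The calibration probe PUC2MM read 11421 ± 889 (SD of 16 spots) on WT_control, 1844 ± 298 on WT_salt, 1176 ± 180 on ABR17_control and 4019 ± 430 on ABR17_salt. After subtraction of the blank mean this was 55.4%, 18.4%, 12.7% and 36.6% of the level of its partner PUC2PM. The calibration probe PUC2PM-20B differed by a larger factor, at 3664 on WT_control, 114 on WT_salt, 115 on ABR17_control and 484 on ABR17_salt. What the calibration probes hold is not given in the sources used here. Of the 11 calibration probes with names ending in 3P, 9 were also dimmer on WT_salt than on WT_control after the blank mean was subtracted, by smaller factors than PUC2MM. The largest falls were those of Ctr04-3P (83.3 against 314), Ctr01-3P (577 against 1792) and Ctr10-3P (364 against 865). The smallest was that of Ctr09-3P (13675 against 14386), and 2 were brighter (Ctr06-3P 1018 against 687, Ctr08-3P 177 against 170). The 6 probes for 5S rRNA were closer, at means of 41895, 48763, 36776 and 46638. WT_control thus stood apart from the rest, and it enters each comparison with the untreated wild type. Over the 30 miRNAs detected everywhere, its levels correlated with those of the other arrays at r = 0.886 to 0.905, while pairs of the other arrays reached 0.929 to 0.965. On ABR17_control the blank spots averaged more than the median miRNA spot (103), which limited detection there.

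**Figure D1:**
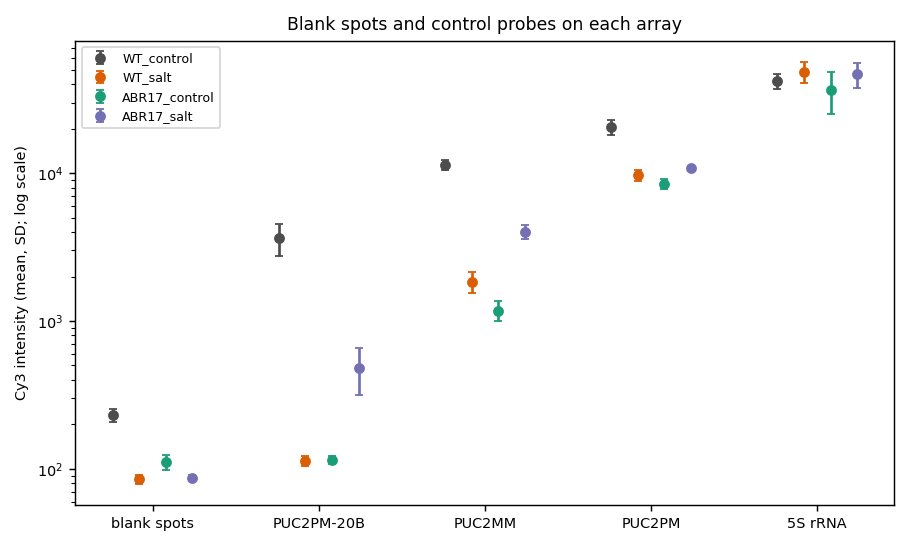
Cy3 intensity on a log axis of blank spots, 3 calibration probes and 5S rRNA probes on the 4 arrays. Points are means, and bars are the SD of repeat spots (for 5S rRNA, of the 6 probe means). Blank spots and PUC2MM were brightest on WT_control, at 231 and 11421.

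Salt in the wild type was examined by WT_salt against WT_control. The probe for miR156h, a member of the SPL-targeting family, was lower with salt by the largest amount: its log2 level was 6.52 on WT_salt and 9.11 on WT_control, a difference of −2.60 ± 0.09 (SE of repeat spots, 6.04-fold lower). Its target sequence lies 1 mismatch from that of the brighter miR157d, which limits what the probe can tell apart. Also lower were miR158a (AT3G10745) at −1.38 ± 0.09, a miRNA of the Brassicaceae, and miR5021 (AT2G08235) at −1.24 ± 0.07. On WT_salt miR156h and miR158a averaged intensities of 104.5 and 101.5, close to the detection threshold of 101.4. The sizes of these 2 differences are therefore uncertain beyond their spot SE. In the authors' deposited values they were −3.28 and −2.5. Higher with salt were miR171a (AT3G51375) at 1.26 ± 0.06, which targets GRAS factors of the HAIRY MERISTEM type, and miR395a (AT1G26973) at no less than 1.28 ± 0.09. The latter targets ATP sulfurylases and a sulfate transporter, and it was not detected on WT_control. These were the 2 higher and 3 lower miRNAs counted among 58 detected on at least 1 of the arrays. Of the 58, 15 gave no value under the rule for bounds. PUC2MM was also lower on WT_salt (1844 against 11421).

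Copper-responsive families were represented by 3 detected members of 6. Both members of miR398, which targets copper/zinc superoxide dismutases, were lower with salt: miR398b by −0.98 ± 0.03 and miR398a by −0.78 ± 0.14. For miR408, which targets copper proteins such as plantacyanin and laccases, the difference was 0.71 ± 0.04. None of these reached the size rule here, and the list median of −0.78 lay at percentile 7.46 of matched random lists. The direction of both miR398 members held under every scaling tried and their size did not, as both lay beyond 2-fold lower under each of the other 5 scalings (miR398a from −1.12 to −2.63, miR398b from −1.14 to −2.75), whereas that of miR408 turned under scaling on the 75th percentile (−0.78), cyclic loess (−0.22), no normalisation (−1.48) and calibration scaling (−0.91). Of the phosphate and sulfate families, 4 of 12 probes were detected on at least 1 array. Besides miR395a, miR395b differed by 0.76 ± 0.10, with overlapping spots and a difference of −0.37 without normalisation.

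The salt families, named before as salt responsive in Arabidopsis, had 22 of 28 members detected on at least 1 array, of which 1 was counted higher (miR171a) and 2 lower (miR156h and miR158a). The median over its 16 members detected on both arrays was 0.00 (percentile 31.7). Phase change families had 1 counted member, miR156h, and a median of 0.00 (percentile 39.0), with miR157a at 0.83 ± 0.33, a value with a wide spread of spots. In the leaf and meristem development families no member was counted. There, miR164c, which targets NAC factors of organ boundaries, differed by 0.70 ± 0.08, and the TCP-targeting miR319c and miR319a by −0.61 ± 0.07 and −0.55 ± 0.07 (list median −0.16, percentile 19.9). The tasiRNA and PPR targeting families had 3 members on both arrays and none counted. These were miR173 at 0.69 ± 0.08 and miR390a at 0.68 ± 0.13, which start the production of trans-acting siRNAs, and miR161.1 at 0.09 ± 0.10 (list median 0.68, percentile 93.0, but −0.11 with calibration scaling and −0.68 without normalisation). None of the 5 members of the auxin signalling families on both arrays was counted (median 0.16, percentile 75.3, but from −0.48 to −1.75 under the 5 other scalings), and none of the 5 in the MYB-targeting families (median 0.00, percentile 36.5). Of the small RNA pathway feedback families, miR168a, which targets ARGONAUTE1, differed by −0.23 ± 0.08. The GRAS targeting families held miR171a and also miR171b, at 0.35 ± 0.13. The NF-Y targeting miR169 probes were detected on WT_salt (4 of 5) and not on WT_control, where the detection threshold was higher (298 against 101). Conserved families had a median of 0.02 (26 members, percentile 58.2) and other families of 0.00 (9 members, percentile 41.0).

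Of the 27 miRNA differences followed through the alternatives in this comparison, 16 turned sign under at least 1, as did 3 of 9 list medians. The direction of miR171a turned without normalisation (−0.69) and with calibration scaling (−0.13), its count was also lost with the 75th percentile and cyclic loess, and that of miR164c, miR390a and miR173 turned under at least 2 of the scalings. The split of 2 higher and 3 lower became 0 and 11 with scaling on the 75th percentile or on the calibration probes, 0 and 17 without normalisation and 4 and 12 in the authors' deposited values, while miR156h and miR5021 were counted under each alternative that gave them a value. All of these alternatives used the same WT_control array, so they do not test its hybridisation. The count of miR395a was lost under 5 of 13 alternatives, among them the 75th percentile (0.71), calibration scaling (0.59) and no normalisation (0.02), and kept under the other 8, among them cyclic loess (1.37) and the authors' deposited values (2.38). That of miR158a was lost with no background correction (−0.98), detection at 6 blank SD (−0.69) and, by a narrow margin, calibration-based detection.

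**Figure D2:**
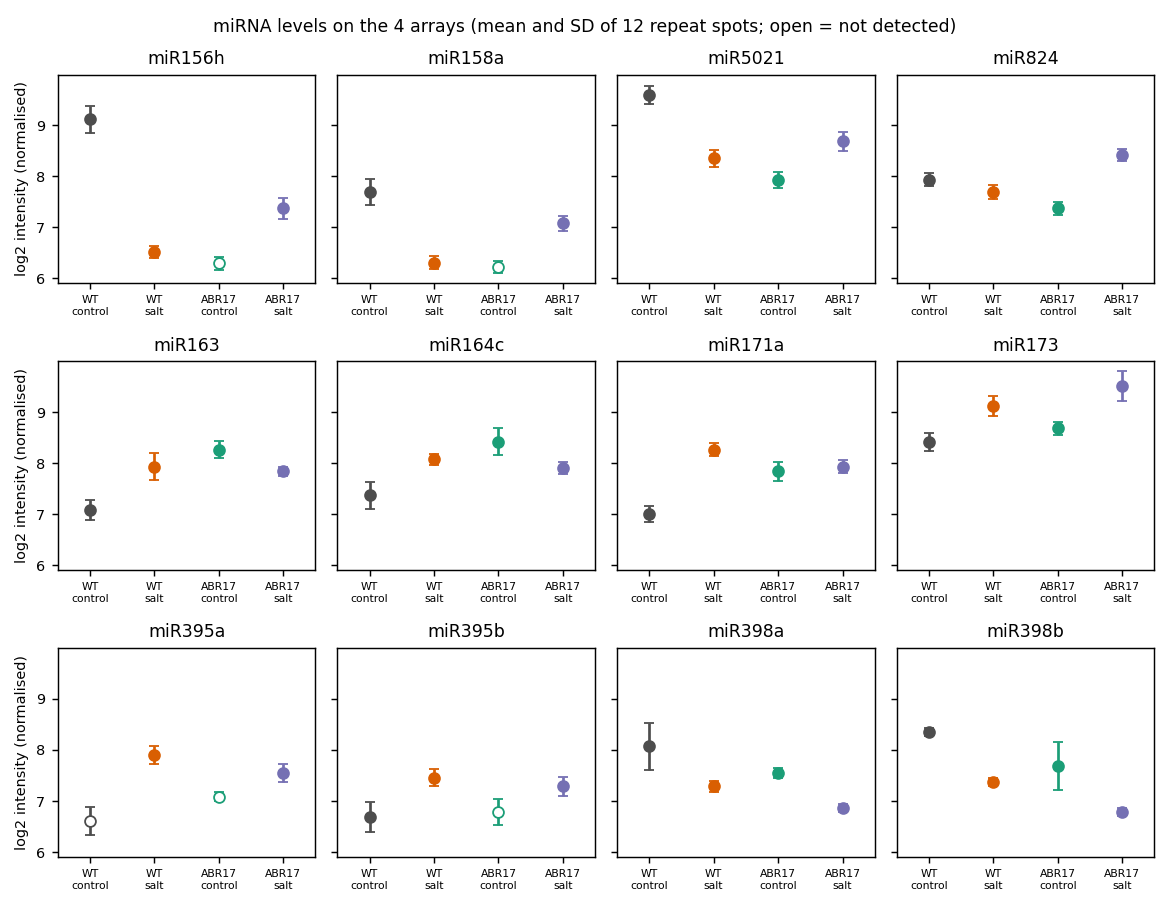
Normalised log2 intensity of 12 miRNAs on the 4 arrays. Points are means and bars the SD of 12 repeat spots, and open points mark miRNAs not detected on that array. On WT_control miR156h stood at 9.11 and miR5021 at 9.59, their highest levels, and both miR398 members were lower on the salt array of each genotype.

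The transgene without salt was examined by ABR17_control against WT_control. The highest difference was that of miR163 (AT1G66725), a miRNA of Arabidopsis and its relatives that targets SAM-dependent methyltransferases of secondary metabolism: 1.18 ± 0.07 (2.27-fold higher in the transgenic). It was joined by miR164c (AT5G27807) at 1.05 ± 0.11. Lower in the transgenic were miR156h, by a bound of −1.83 ± 0.09 since it was not detected on ABR17_control, and miR5021 at −1.66 ± 0.07. Thus 2 miRNAs were counted higher and 2 lower among 39 detected on at least 1 of the arrays. Of the 39, 7 gave no value under the rule for bounds. PUC2MM was lower on ABR17_control as well (1176 against 11421).

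Among the leaf and meristem development families, 1 of 6 members on both arrays was counted higher (miR164c). Its relative miR164a differed by 0.89 ± 0.07 and miR319c by −0.71 ± 0.08 (list median 0.00, percentile 33.1). The 2 members of the GRAS targeting families detected on both arrays differed by 0.84 ± 0.07 (miR171a) and 0.55 ± 0.07 (miR171b), and neither was counted. Both turned negative with the 75th percentile (−0.17 and −0.10) and without normalisation (−0.57 and −0.50). In the auxin signalling families, miR167a, which targets the auxin response factors ARF6 and ARF8, differed by 0.66 ± 0.06 and miR390a by 0.46 ± 0.06, with no member counted (5 members, median 0.35, percentile 83.6). That median turned negative under 4 scalings, among them cyclic loess (−0.07) and the 75th percentile (−0.55). Copper families had a median of −0.52 (3 members, percentile 14.8), with miR398b at −0.66 ± 0.14, miR398a at −0.52 ± 0.13 and miR408 at 0.10 ± 0.05, the last turning negative under all 5 other scalings (from −0.43 to −1.59).

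The salt families had 1 member counted, miR156h, and a median of 0.03 over 14 (percentile 58.0). For phase change families the same miRNA was counted, and the median was −0.04 over 4 members (percentile 17.2), with miR157a at 0.91 ± 0.32. No member was counted in the MYB-targeting families (5 members, median 0.00, percentile 39.4), with miR159b at 0.23 ± 0.05, or in the tasiRNA and PPR targeting families (3 members, median 0.26, percentile 78.5, but −0.13 with cyclic loess, −0.32 with calibration scaling, −0.56 with the 75th percentile and −0.96 without normalisation). In the small RNA pathway feedback families, the difference of miR168a was 0.00 ± 0.06, a tie of rank (0.06 in the authors' deposited values). Of the phosphate and sulfate families and the NF-Y targeting family no member was detected on both arrays. Conserved families had a median of 0.03 (24 members, percentile 56.4), and other families of −0.03 (6 members, percentile 18.8), where miR824 differed by −0.56 ± 0.05. Here 16 of 26 miRNA differences and 5 of 9 list medians turned sign under at least 1 alternative. The difference of miR164c was −0.22 without normalisation. Both miRNAs counted higher were lost with no background correction, the 75th percentile, no normalisation and calibration scaling (miR163 at 0.96, 0.52, 0.12 and 0.77), and miR164c also with cyclic loess (0.87) and the median of repeat spots. The 75th percentile left 0 higher and 9 lower, and the authors' deposited values gave 5 higher and 6 lower.

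Salt in the transgenic was examined by ABR17_salt against ABR17_control. The 1 miRNA counted was miR824 (AT4G24415), which targets the MADS-box gene AGAMOUS-LIKE16, a gene of stomatal development and flowering time: it was higher with salt by 1.05 ± 0.05 (2.07-fold). No miRNA was counted lower among 59 detected on at least 1 of the arrays, of which 27 gave no value under the rule for bounds. The largest negative differences were those of miR398b (−0.90 ± 0.14), miR167a (−0.76 ± 0.06) and miR398a (−0.68 ± 0.04), and the largest positive ones after miR824 were those of miR173 (0.83 ± 0.09), miR5021 (0.75 ± 0.07) and miR319c (0.71 ± 0.06). These 6 directions held under every scaling tried. PUC2MM was also higher on ABR17_salt (4019 against 1176).

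The copper list had a median of −0.68 over 3 members (percentile 4.29), with miR408 at 0.07 ± 0.04. Sulfate-related miR395a was detected with salt and not without, and its difference was no less than 0.26 ± 0.06. The 6 members of other families on both arrays had a median of 0.45, at percentile 99.4. They comprised miR824, miR173 and miR5021, then miR161.1 at 0.15 ± 0.08 and miR163 at −0.43 ± 0.05, and miR854a. Leaf and meristem development families went both ways, with miR319c higher by the value above and miR164a and miR164c at −0.66 ± 0.05 and −0.52 ± 0.08 (6 members, median −0.05, percentile 46.0). The auxin signalling families had a median of −0.07 (5 members, percentile 37.5), with miR167d at −0.35 ± 0.05. The GRAS targeting miR171b differed by −0.55 ± 0.06 and miR171a by 0.09 ± 0.06. The salt families had a median of −0.04 over 14 members (percentile 42.8), phase change families of −0.09 over 4 (percentile 33.3), MYB-targeting families of 0.00 over 5 (percentile 54.9), tasiRNA and PPR targeting families of 0.15 over 3 (percentile 88.5) and conserved families of −0.08 over 24 (percentile 24.9), none with a counted member. In the small RNA pathway feedback families miR168a was at 0.00 ± 0.06, a tie of rank (0.30 in the authors' deposited values). Of the 5 NF-Y targeting miR169 probes, 4 were detected on ABR17_salt and none on ABR17_control. These calls fix no direction, as the detection thresholds were 98.3 on ABR17_salt and 151 on ABR17_control. The normalised log2 levels of these 4 were lower on ABR17_salt (miR169a 6.37 against 6.61). With no background correction, detection at 6 blank SD or calibration scaling miR824 was not counted, and the last of these gave 0 higher and 4 lower. In this comparison 7 of 28 miRNA differences and 3 of 9 list medians turned sign under at least 1 alternative.

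The transgene under salt was examined by ABR17_salt against WT_salt, the pair with the most miRNAs detected on both arrays (51). No miRNA was counted higher or lower among 62, of which 3 gave no value under the rule for bounds. The largest differences were those of miR156h (0.85 ± 0.07), miR158a (0.77 ± 0.06), miR824 (0.73 ± 0.05) and miR319c (0.61 ± 0.06) on the higher side, and of miR398b (−0.58 ± 0.03) and miR408 (−0.54 ± 0.04) on the lower side. The WT_salt levels of miR156h and miR158a lay close to the detection threshold, so the sizes of their differences are uncertain. PUC2MM was higher on ABR17_salt (4019 against 1844). Normalising these arrays without WT_control left the counts at 0 and 0, and those of salt in the transgenic at 1 and 0. Other alternatives counted miRNAs as higher in the transgenic under salt: 6 with the authors' deposited values, 3 without normalisation, 2 with a normexp offset of 16 and 2 with the blank mean subtracted. For this pair, 18 of 36 miRNA differences and 6 of 13 list medians turned sign under at least 1 alternative.

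All 3 detected members of the copper families were lower in the transgenic under salt, miR398a by −0.42 ± 0.04, and the list median of −0.54 lay at percentile 0.435 of matched lists. This was the lowest of 40 list percentiles. The sequences of miR398a and miR398b lie 1 mismatch apart, so the pair is not 2 separate readings, and this limits the copper list in every comparison. The difference of miR408 was 0.13 without normalisation. The phosphate and sulfate families had a median of −0.17 over 3 members (percentile 17.6), with miR395a at −0.35 ± 0.07 and miR395b at −0.17 ± 0.07, the latter turning positive under cyclic loess (0.12) and without normalisation (0.19). GRAS targeting families had a median of −0.33 over 3 members (percentile 5.05), with miR171a at −0.33 ± 0.05, which turned to 0.14 without normalisation, where the median was −0.054. Medians of the remaining lists were within 0.16 of 0: salt families 0.00 (21 members, percentile 79.1), auxin signalling −0.16 (5, percentile 23.3), phase change −0.07 (6, percentile 34.4), leaf and meristem development 0.11 (6, percentile 84.8), MYB-targeting 0.14 (5, percentile 84.2), small RNA pathway feedback 0.14 (3, percentile 84.1), NF-Y targeting −0.0045 (4, percentile 49.2), tasiRNA and PPR targeting 0.00 (3, percentile 62.2), conserved −0.08 (36, percentile 33.7) and other families 0.05 (15, percentile 92.2).

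The salt responses of the genotypes were then set against each other. Their difference (transgenic minus wild type) reached the size rule for 9 miRNAs. It was positive for miR156h (2.68, partly a bound), miR5021 (2.0), miR319c (1.32) and miR824 (1.29), and negative for miR163 (−1.27), miR164c (−1.22), miR171a (−1.17), miR157a (−1.06) and miR164a (−1.04). A 10th, miR395a, passed the rule at −1.02 only as a difference between bounds, which fixes no size, and its measured responses differed by −0.83. These 6 negative differences turned positive without normalisation, and the 4 positive ones held their sign under every scaling tried. Every one of them includes the WT_control array. The 4 positive ones were lower with salt in the wild type and higher in the transgenic. PUC2MM moved in the same directions (11421 to 1844, and 1176 to 4019). The reverse held for miR163, miR164c, miR157a and miR164a, while miR171a was higher with salt in both genotypes. The scalings do not act on single probes, so a held sign cannot tell a difference in hybridisation from a salt response. Across the 30 miRNAs detected on all 4 arrays, the salt responses of the genotypes correlated at r = −0.08 (SD 0.04 over resampled spots) with a Spearman rho of −0.04. Under cyclic loess r was −0.29. The miR398 members had differences of the same sign in both genotypes, of similar size under the main processing but not under others (miR398a −2.63 and −0.34 without normalisation, −2.01 and −0.90 in the authors' deposited values).

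**Figure D3:**
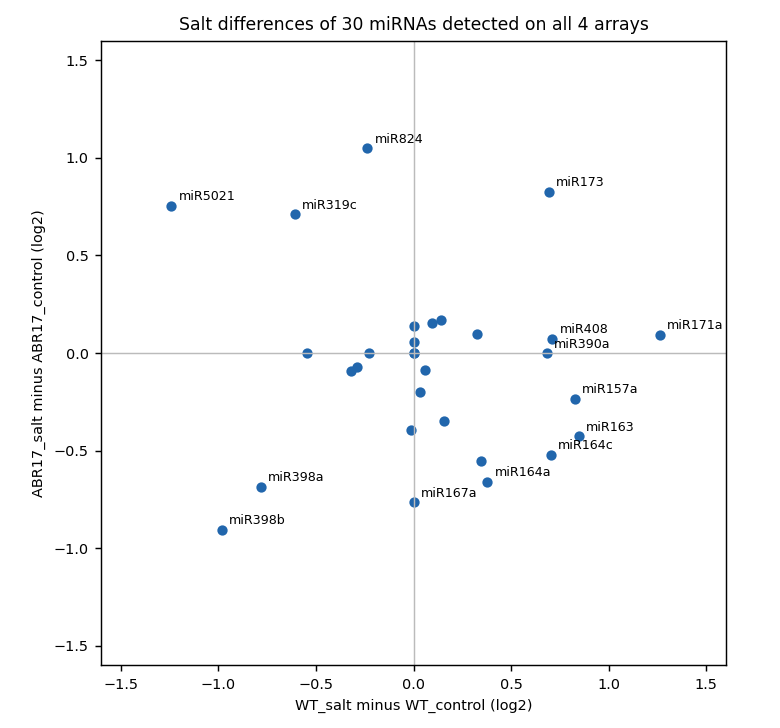
Log2 difference with salt in the wild type (horizontal) and in the transgenic (vertical) for the 30 miRNAs detected on all 4 arrays, 1 point each, with names for differences of at least 0.6 in either genotype. The cloud had no common trend (r = −0.08), with miR398a and miR398b low in both and miR5021 and miR319c on opposite sides.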

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

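The tests weighed in this part were all chosen after the results were seen, and so were the limit of 0.5 log2 for the miRNAs grouped here and the limit of 4 mismatches. Of 6 miRNAs whose difference with salt exceeded 0.5 in both genotypes, 3 had the same sign (miR398a, miR398b and miR173). In the wild type the sign of miR173 turned without normalisation (−0.68) and with calibration scaling (−0.11). For the other 3 of the 6, the difference with salt lay on opposite sides in the genotypes. For miR5021 it was −1.24 in the wild type and 0.75 in the transgenic, a difference of 2.0 between the responses. For miR319c the values were −0.61 and 0.71, a difference of 1.32. For miR164c they were 0.70 and −0.52, a difference of −1.22, but in the wild type its sign turned with the 75th percentile (−0.51), calibration scaling (−0.64) and no normalisation (−1.20). With 1 array per group none of these differences was tested.

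Several calibration probes, which enter no comparison, were bright. PUC2MM exceeded the blank mean by 11190 on WT_control. A few of the dimmest members of the calibration series passed the detection rule on some arrays, by the share of their spots above the threshold. Ctr03-3M05 exceeded the blank mean by 381 on WT_control, 19.1 on WT_salt and 26.5 on ABR17_salt. Ctr03-3M10 did so by 120 on WT_control and 14.4 on WT_salt, and Ctr01-3M05 by 15.4 on WT_salt, where the means of these 2 probes lay below the threshold.

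The miRNAs lower on WT_salt than on WT_control by over 0.5 form a pattern of 10: miR156h, miR158a, miR5021, miR319c, miR319a, miR398a and miR398b, and also miR158b, miR391 and miR834, named here after their values were seen. Neither salt nor hybridisation is excluded, as the members split in the transgenic: of the 5 detected on both ABR17 arrays, 2 (miR5021 and miR319c) were higher on ABR17_salt, miR319a was level and both miR398 members were lower. A difference in hybridisation as read by PUC2MM, an undescribed calibration probe that was higher on ABR17_salt, may account for part of the pattern. The median measured difference of ABR17_salt from ABR17_control was 0.25 (spot SE 0.07) over all 10, of which 5 were undetected on 1 or both ABR17 arrays. Over the 5 detected on both it was 0, the value of miR319a, which is a tie of rank. A salt response changed by the transgene stays open, as the median difference of responses of 0.84 decides nothing: the members were picked for a low wild type response, which favours a positive value, and these explanations cannot be told apart with 1 array per group. Uptake of brighter near-identical miRNAs also stays open: 5 of 10 had a brighter probe within 4 mismatches, against 10 of 29 others (two-sided Fisher's exact test, p = 0.46).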

How the results depend on the processing

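The alternatives with the blank mean subtracted, calibration scaling, normalisation without WT_control and calibration-based detection were chosen after seeing the data. No paired analysis was possible because each group had 1 array and the labels give no shared replicate numbers. Of the alternatives set beforehand, subtraction of a background column and quantile normalisation over all non-control probes were not run, as the array files hold no background column and no such other probes. Detection on at least 1 array was reached by 63 of 213 miRNAs, and whether the rest were absent or too dim was not tested. The counts of miR156h and miR5021 held in both comparisons with WT_control under every alternative that gave them a value (−3.28 to −1.73 and −2.54 to −1.15 for salt in the wild type). All of these alternatives used the same WT_control array and none acts on single probes. They therefore do not test a difference in hybridisation. Of the single miRNA and list values, 1795 stayed within the spot spread, 542 moved and 9 changed sign after being counted. The alternatives that change only the detection rule or the spot requirement reuse the main normalised values. Under these a miRNA that stays detected on both arrays cannot move. The totals therefore overstate how well the values held. Sign changes were more common among all of these values, counted or not: 182 of 2346, from 63 of 127 miRNA differences and 17 of 40 list medians. Where no construction is named, the cause was not tested.

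Counts that moved are given as higher or lower, in the order salt in the wild type (2 higher and 3 lower in the report), transgene without salt (2 and 2), salt in the transgenic (1 and 0) and transgene under salt (0 and 0). Without background correction, higher counts were 1, 0 and 0 in the first 3 comparisons, and 6 differences of salt responses were counted instead of 10 (9 without miR395a, which lies between bounds). A normexp offset of 16 gave 5 higher for the transgene without salt, 1 lower for salt in the transgenic and 2 higher for the transgene under salt. Scaling on the 75th percentile gave 0 higher and 11 lower, 0 higher and 9 lower, and 1 lower in the first 3. Cyclic loess gave 5 and 4 lower in the first pair of comparisons and r = −0.29 between the salt responses.

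Without normalisation, 0 were higher and 17 lower, then 0 higher and 12 lower, 3 were higher for the transgene under salt, and 16 differences of responses were counted. There miR171a turned to −0.69 with salt in the wild type and miR164c to −0.22 for the transgene without salt. Differences of responses turned to 0.064 (miR163), 0.35 (miR164c), 0.71 (miR171a), 0.27 (miR157a), 0.45 (miR164a) and 0.29 (miR395a). The authors' deposited values gave 4 higher and 12 lower, 5 higher and 6 lower, 3 higher and 4 lower, and 6 higher under salt, with no spot requirement. The median of repeat spots gave 1 higher for the transgene without salt. Detection on all 4 arrays, which tests fewer miRNAs, gave 1 higher and 1 lower for salt in the wild type and 1 lower for the transgene without salt. No detection filter gave 2 higher for salt in the transgenic, and detection at 6 blank SD gave 1 higher for salt in the wild type and 0 in the transgenic.

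Subtraction of the blank mean gave 4 higher and 4 lower for the transgene without salt, 3 higher and 1 lower for salt in the transgenic and 2 higher under salt. Calibration scaling gave 0 higher and 11 lower, 0 higher and 7 lower, and 0 higher and 4 lower in the first 3, with miR171a at −0.13. Calibration-based detection gave r = −0.031. Scalings also moved the median over all 213 miRNAs by more than 0.1, in the same order: 0.41 and, under salt, −0.59 with the 75th percentile; −0.28, −0.48 and, under salt, −0.15 without normalisation; 0.28, 0.17, −0.28 and −0.40 with calibration scaling; and −0.25 and −0.16 in the last pair with the deposited values.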

Other observations

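The tests in this part were chosen after the results were seen, and so was the 4-fold limit used for the deposited table. A set of dim miRNAs was detected on both salt arrays and on neither control array. It held 16 miRNAs, among them miR169a, miR169b, miR169d and miR169h, which target NF-YA factors, miR403 and miR162a, which target the small RNA machinery genes ARGONAUTE2 and DICER-LIKE1, miR394a, which targets an F-box gene of leaf development, and the sulfate and phosphate miRNAs miR395a and miR399b. Also among them were miR472, which targets disease resistance genes, and miR822 and miR823, and these 3 and miR394a are named here after their values were seen. No miRNA was detected on both control arrays and on neither salt array. The detection thresholds were 298 and 151 on WT_control and ABR17_control and 101 and 98.3 on WT_salt and ABR17_salt, so the control arrays required brighter spots. With the threshold set from the dimmest calibration probes the numbers detected were 39 on WT_control, 35 on WT_salt, 39 on ABR17_control and 50 on ABR17_salt, against 39, 54, 30 and 59 with blank spots.

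In the authors' deposited table, miR398a stood at 272 on WT_control and 67.3 on WT_salt, and at 96.0 on ABR17_control and 51.5 on ABR17_salt. In the same table miR395a stood at 24.6 and 169 in the wild type and at 48.8 and 113 in the transgenic. The genotype differences of the media did not run together either: across the 30 miRNAs detected on all arrays, the transgenic minus wild type difference without salt correlated with that under salt at r = −0.33 (rho −0.34), on these arrays and with miRNAs that are not independent replicates.

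On the salt array of each genotype, miR395a and miR395b were brighter and miR398a and miR398b dimmer. Scaling between arrays stays open for miR398 although 0 of 20 differences (4 under each of 5 settings) turned their sign: in the transgenic 7 of 10 moved towards 0 without turning, but in the wild type 0 of 10 did, so no turn could be seen there. For miR395 it stays open as well, as 1 of 20 turned, that of miR395b in the wild type without normalisation (−0.37), and the miR395 probes lay below the detection threshold on 1 or both control arrays. Hybridisation was not tested and stays open, since these miRNAs were picked for having the same sign in both genotypes, and the sequence of miR398a lies 1 mismatch from that of miR398b, so the pair is not 2 separate readings. Salt lowering miR398 in both genotypes is 1 of the open explanations, untested with 1 array per group.

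Large differences of dim miRNAs in the authors' deposited table formed a further pattern, found after its values were seen. By at least 2-fold, 42, 30, 36 and 29 miRNAs differed there in the comparisons as ordered in the report, of which 25, 15, 20 and 22 were detected on neither array. Of the dim miRNAs that differed by at least 4-fold, 11 of 12 cases had 1 spot over 2 times as bright as the next on the higher array, so a single bright spot could account for most of them. On WT_salt the brightest spot of miR400 read 759 and the next 103, and on ABR17_control that of miR414 read 1099 and the next 113. The exception was miR2112-5p, and no biological explanation was tested.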
